A study of Rattus norvegicus with 10 samples.

How the data were processed

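Rat knee cartilage was profiled by stranded, paired-end messenger RNA sequencing. The blade-dissected joint surface was the source of RNA, per the labels' protocols, and the library kit was TruSeq. The 10 libraries fall into 4 groups: 2 from healthy, untreated cartilage (HC), 3 taken 4 weeks after papain and L-cysteine were injected into the joint (OAC), 3 taken 10 weeks after papain with a GFP-carrying adeno-associated virus given at 4 weeks (SHAM), and 2 taken 10 weeks after papain with a mix of vectors carrying αKlotho and soluble TGF-beta receptor 2 given at 4 weeks (KT). Papain is a protease that strips proteoglycan from cartilage, and the injection is a chemical model of osteoarthritis. Each label gives an age of 5 months, whatever the interval since injection. Nothing in the labels says that the libraries of a group came from separate animals, so the p-values measure the spread between these libraries, which may be technical in part.

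The deposited expression table holds FPKM (fragments per kilobase of exon and per 1000000 fragments) for 17419 RefSeq transcripts in each library. The submitters' processing notes name FastQC 0.11.2, STAR 2.5.3a, HOMER (its version is not given in the sources used here), DESeq2 1.18.1 and the rat genome build rn6. Per the file headers, the authors counted reads over exons with HOMER, with the strand option set to minus, kept 1 transcript per gene, and tested the groups with DESeq2. Their deposited comparison table gives a log2 fold change, a p-value and an adjusted p-value in 4 pairs of groups, without KT against HC or OAC, and 2910 to 3021 of its transcripts have no fold change listed in a given pair. The name of the counts it was made from, kept in its header, holds a word for removal, so libraries may have been left out before deposit, and which is not given in the sources used here. Both tables list 17419 transcripts, of which 17098 identifiers occur in both. Transcript positions are those of the deposited table, in rn6, 1-based. No count table was used here, so a count model was not the main test.

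Depth was read back from the low values. With whole reads, the smallest step of a library's FPKM multiplied by exon length in kilobases is the value of 1 read, and this step was found per library by a search over 8000 trial values between 0.01 and 0.03. Among values below 1000 reads of transcripts shorter than 3000 bases, 100% came out within 0.15 of a whole read in every library, against 30% by chance. In units of 1000000 reads, the recovered totals were 52.4 to 70.9 per library, of which 32.1 to 44.5 (58.6 to 64.4%) lay on listed genes. The authors' command line, kept in the header of the comparison table, gives run names with 3 distinct tags. Tag 2 occurs only among the disease libraries, in 2 of 3, and the tags cannot be tied to single libraries within a group, so no value within a sequencing batch can be given and a batch is in part confounded with OAC.

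Changes were tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1) with an intensity trend, in a single fit of all 10 libraries with group as the only term, for the 11282 genes with a mean of at least 0.5 FPKM. Tests were two-sided and adjusted by Benjamini-Hochberg, and a gene was called at an adjusted p under 0.05. Log2 changes are on the log2(FPKM + 1) scale, which understates the change of low genes. Changes given as fold or times are ratios of the mean FPKM of the groups. A further 2664 transcripts were at 0 in every library. Before the data were examined, 34 gene lists, 16 focus genes, the tests, the alternatives and the rule for named genes were fixed. The lists cover cartilage matrix and its regulators, joint tissues, signalling pathways, general cell states and markers of other cell types that a blade could take along. Of 908 list entries 858 matched a gene in the table, and the 33 lists with at least 5 measured members were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation beside it. Limma's fry, which does not compare a list with the other genes, was also run on the lists. The list of keratinocyte and skin markers had fewer than 5 measured members and was not tested. Counts over a list were also made with p-values adjusted over the list alone. Whether genes changed at 4 weeks moved the other way under treatment was tested with limma's fry.

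Genes were named by rule: in each of the 3 main comparisons, the 10 largest changes in each direction among called genes with a known symbol, a mean of at least 1 FPKM in the higher group and no overlap between the libraries of the groups, up to 4 called members of each list that was called or held a called gene, and the focus genes at any value. Genes named outside this rule, which are the comparison of KT with OAC and members of a list beyond its first 4, were chosen after their values were seen. Of the focus genes, 15 were in the table and 14 passed the filter. Col10a1 is not analysed here, and results of some genes under the rule are not reported here.

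The gene and list tests and the reversal difference of medians were checked on simulated data drawn for the 11282 tested genes. For the gene test 200 genes were changed by log2 sizes of 1 to 4. For OAC against HC, 86% of genes changed by 1 and 98% of those changed by 2 were called. For SHAM against OAC the shares were 80% and 98%, and for KT against SHAM 82% and 94%. Among unchanged genes 6, 13 and 8 were called in these comparisons. Both of the 2 changed lists were called and 0 others, and a simulated reversal of 2 came out at 1.99. Limma's fry, which tested the reversal, was not checked in this way. Genes were drawn independently of each other, so this check does not cover false list calls from correlated members. Exact binomial 95% intervals of ratios of recovered reads cover counting error only. Bootstrap 95% intervals of a median resampled its genes 2000 times, so they carry no spread between libraries.

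The alternatives were pseudocounts of 0.1 and 5, no filter and a filter at 5 FPKM, quantile and median-of-ratios scaling, a fit of only the groups compared, array weights, no intensity trend, the replicate number as a block, each library left out in turn, a minimum log2 change of 1, the authors' table, an estimated correlation between list members, and the 200 genes of smallest p per direction for the reversal. Added after the data were seen were limma's voom on the recovered reads, a fit without the haemoglobin transcripts, a marrow score as a covariate, and the Klotho and FGF axis list without Kl. No pair of libraries held identical values. Within groups the correlation of log2 values across genes was 0.913 to 0.988, lowest for the HC pair. Figures were drawn with matplotlib.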

Results

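Knee cartilage of rats was sequenced in 10 libraries: 2 from healthy, untreated joints (HC), 3 from joints 4 weeks after papain and L-cysteine (OAC), 3 from joints 10 weeks after papain that received a GFP vector at 4 weeks (SHAM), and 2 from joints 10 weeks after papain that received vectors for αKlotho and soluble TGF-beta receptor 2 at 4 weeks (KT). In units of 1000000 reads, the recovered depth was 52.4 to 70.9 per library, with 32.1 to 44.5 on listed genes. Values are FPKM given as mean ± SD, log2 changes are on the log2(FPKM + 1) scale, and changes given as fold or times are ratios of mean FPKM. The study was set up to follow expression through disease progression and under treatment.

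Cartilage 4 weeks after papain was first set against healthy cartilage, with a sequencing batch in part confounded with OAC. Genes of matrix breakdown were higher after injury. Mmp13, the collagenase that cleaves type II collagen (NM_133530, chromosome 8 from 5522739 to 5533018 in rn6), rose from 69.8 ± 2.6 FPKM in HC (SD, n = 2) to 579 ± 328 in OAC (SD, n = 3), 8.3 times the healthy mean (limma, Benjamini-Hochberg adjusted p = 0.0091). Mmp3, a stromelysin that degrades proteoglycan, rose 4.91-fold, from 28.1 ± 9.5 to 138 ± 30.3 FPKM. Among 26 measured matrix proteases 17 rose, 0 fell and 9 did not pass, with 19 higher when adjusted over the list alone. Their median log2 change was 0.94 (camera, Benjamini-Hochberg adjusted p = 0.00011), and adjusted p = 0.61 with an estimated correlation.

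Cartilage matrix genes went both ways. Col2a1, the main cartilage collagen (NM_012929, chromosome 7 from 139455242 to 139483997), rose 4.1-fold, from 970 ± 343 FPKM in HC (SD, n = 2) to 3980 ± 1070 in OAC (SD, n = 3), and Col9a1, which coats type II fibrils, rose 8.05-fold. Acan, the large aggregating proteoglycan that papain strips from the tissue (NM_022190, chromosome 1 from 140762758 to 140824441), was 1.98 times lower, at 205 ± 32.3 against 405 ± 77.7 FPKM (limma, Benjamini-Hochberg adjusted p = 0.0069). Frzb, a secreted Wnt antagonist of articular chondrocytes, was 2.63 times lower, and the lubricant gene Prg4 was 2.54 times lower at 1260 ± 245 against 3210 ± 1610 FPKM. Of 36 measured members of the cartilage matrix and chondrocyte list, 3 rose, 9 fell and 24 did not pass, and 3 rose and 12 fell when adjusted over the list alone. The list median was -0.27 (camera, Benjamini-Hochberg adjusted p = 0.00032), and adjusted p = 0.66 with an estimated correlation. Sox9, the chondrocyte transcription factor, stood at 12.7 ± 3.45 against 19.9 ± 2.68 FPKM and missed the threshold (limma, Benjamini-Hochberg adjusted p = 0.085), but passed with quantile normalization (adjusted p = 0.042) and with median-of-ratios scaling (adjusted p = 0.049). Prg4 lost its call without HC replicate 2, where its log2 change went from -1.27 to -0.73 (limma, Benjamini-Hochberg adjusted p = 0.15), without OAC replicate 1 (0.07) and without OAC replicate 3 (0.066).

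**Figure D1:**
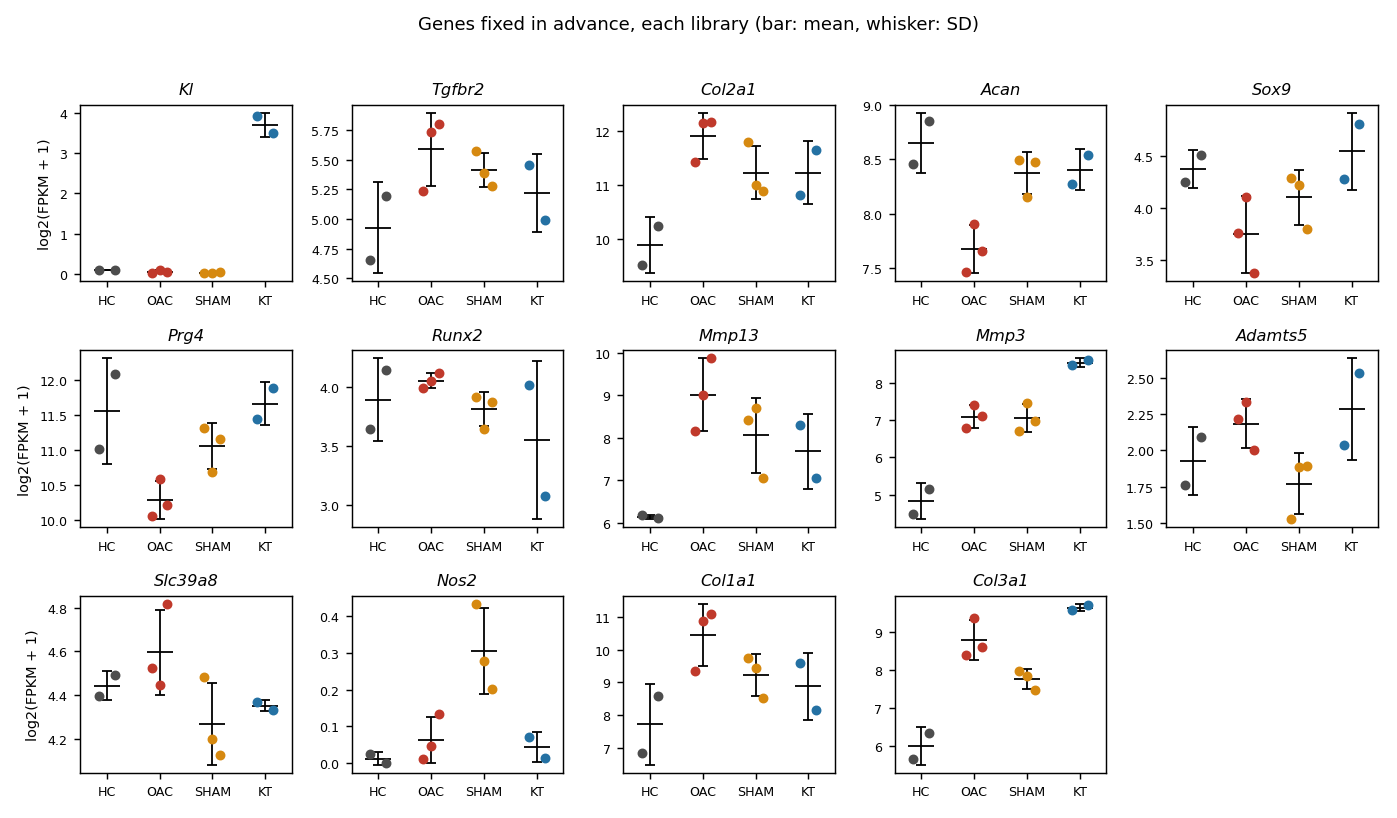
Expression of focus genes found in the table, as log2(FPKM + 1) per library (points) with the group mean and SD, by group on the x axis (HC n = 2, OAC n = 3, SHAM n = 3, KT n = 2). Kl stands far above the other groups in KT alone, at 12.2 FPKM, and Col2a1 is higher in OAC than in HC, at 3980 against 970 FPKM.

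Most osteoclast markers and some fibrous matrix genes were also higher in OAC. Col3a1, a collagen of fibrous tissue, rose 7.05-fold, from 65.6 ± 22.4 FPKM in HC (SD, n = 2) to 463 ± 178 in OAC (SD, n = 3; limma, Benjamini-Hochberg adjusted p = 0.0011). In the fibrous matrix list 8 of 22 measured members rose and 14 did not pass, with 10 higher when adjusted over the list alone, and the list itself missed the threshold (camera, Benjamini-Hochberg adjusted p = 0.07). Acp5 and Ctsk, the phosphatase and cathepsin that osteoclasts use to resorb bone, reached 1460 ± 843 and 1750 ± 857 FPKM against 140 ± 91.1 and 196 ± 138 in HC, 10.4 and 8.89 times the healthy means. Of 16 measured osteoclast markers 12 rose and 4 did not pass (13 adjusted over the list alone; median 1.45; camera, Benjamini-Hochberg adjusted p = 0.00075), and adjusted p = 0.66 with an estimated correlation. Without HC replicate 1 the log2 change of Acp5 went from 3.30 to 2.59 (limma, Benjamini-Hochberg adjusted p = 0.12) and that of Ctsk from 3.20 to 2.41 (0.051). Acp5 also lost its call without OAC replicate 2 (log2 change 3.02, adjusted p = 0.077) or OAC replicate 3 (2.93, adjusted p = 0.073).

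Blood and marrow markers moved with these groups. Camp, an antimicrobial peptide of neutrophil granules, rose 6.87-fold, from 124 ± 6.94 FPKM in HC (SD, n = 2) to 848 ± 92.1 in OAC (SD, n = 3), and S100a8 rose 6.27-fold. Of 20 measured neutrophil and marrow genes 18 rose and 2 did not pass, or 19 when adjusted over the list alone (median 2, camera, Benjamini-Hochberg adjusted p = 8.4e-08), and adjusted p = 0.61 with an estimated correlation. Of 16 erythroid genes 12 rose, 14 when adjusted over the list alone (median 1.23, camera, Benjamini-Hochberg adjusted p = 0.00058), and adjusted p = 0.66 with an estimated correlation. Macrophage markers rose in 18 of 25 cases and 19 adjusted over the list alone (median 1.05, adjusted p = 8.6e-06 by camera with Benjamini-Hochberg), and adjusted p = 0.61 with an estimated correlation. Lymphocyte markers rose in 15 of 24 cases and 19 adjusted over the list alone (median 0.91), with the same preset p and adjusted p = 0.45 with an estimated correlation. Top2a, a topoisomerase of dividing cells, rose 3.65-fold with 32 of 33 cell cycle genes, 33 adjusted over the list alone (median 1.38, camera, Benjamini-Hochberg adjusted p = 2.1e-11), and adjusted p = 0.61 with an estimated correlation. A marrow score made of the neutrophil and erythroid lists was used as a covariate, a test added after the data were seen. With it limma called 0 of the 3348 changed genes at a Benjamini-Hochberg adjusted p under 0.05. The lowest was 0.098, with 2157 genes at an unadjusted p under 0.05. The directions of the cell cycle, cartilage matrix and TGF-beta receptor lists turned, and the cartilage matrix list was called in the other direction. The erythroid list turned too, but it is part of the score, so its turn was no independent result.

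**Figure D2:**
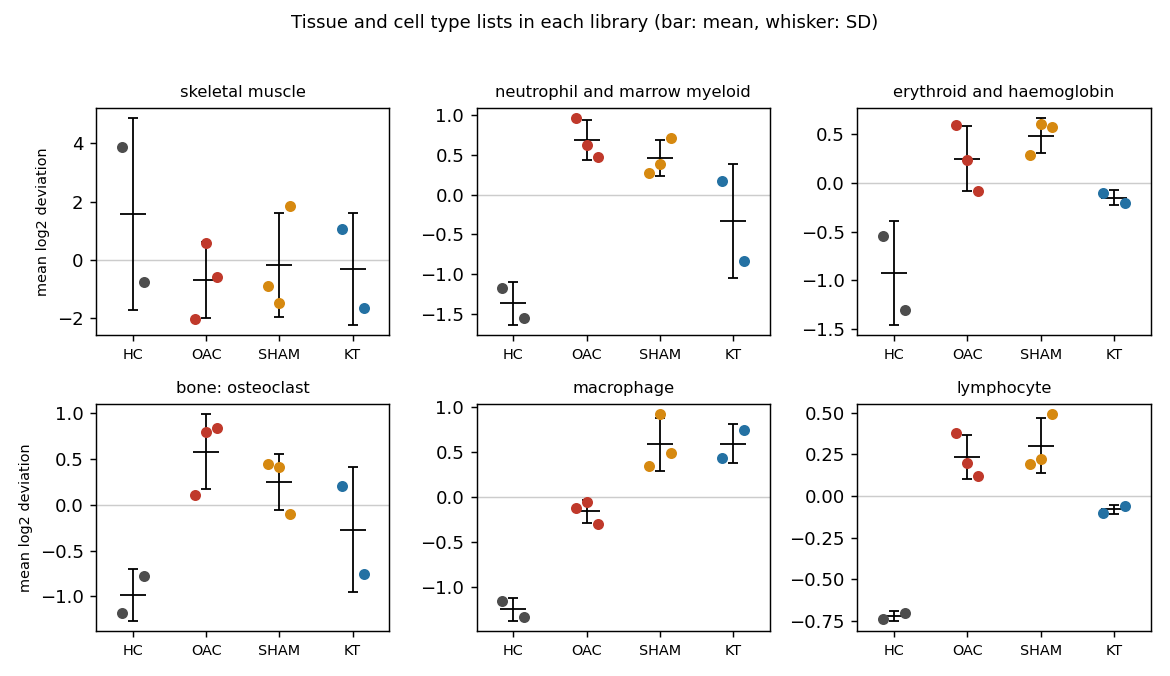
Mean log2 deviation of the members of 6 tissue and cell type lists from their mean over all libraries, per library (points) with group mean and SD. The skeletal muscle score of HC replicate 1 stands at 3.89 against -0.76 in HC replicate 2, and neutrophil and marrow scores lie below 0 in both HC libraries.

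Muscle markers set the HC libraries apart. The score of the skeletal muscle list was 3.89 in HC replicate 1 and -0.76 in HC replicate 2, and 1.85 in SHAM replicate 3 and 1.06 in KT replicate 1. In OAC against HC 0 of its 33 measured members rose and 1 fell, Tcap, a muscle sarcomere gene (0 adjusted over the list alone), at a list median of -2.77 (camera, Benjamini-Hochberg adjusted p = 9.9e-06), and adjusted p = 0.66 with an estimated correlation. Tcap lost its call without HC replicate 1, where its log2 change went from -3.17 to -1.49 (limma, Benjamini-Hochberg adjusted p = 0.15), OAC replicate 1 (0.08) or OAC replicate 3 (0.066). Oxidative phosphorylation genes, with a median of -0.09 (camera, Benjamini-Hochberg adjusted p = 0.012), and adjusted p = 0.85 with an estimated correlation, were called in the other direction without HC replicate 1.

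Further lists were called in OAC against HC. Interferon response genes rose in 13 of 28 cases and 14 adjusted over the list alone, among them Rsad2, an antiviral enzyme, 3.12-fold, and the immunoproteasome subunit Psmb8, 2.47-fold (camera, Benjamini-Hochberg adjusted p = 0.0048), and adjusted p = 0.66 with an estimated correlation. Complement genes rose in 12 of 26 cases and 12 adjusted over the list alone, with Plaur, the urokinase receptor, at 13.4 ± 0.428 FPKM in OAC (SD, n = 3) against 4.1 ± 0.664 in HC (SD, n = 2; camera, Benjamini-Hochberg adjusted p = 0.04), and adjusted p = 0.61 with an estimated correlation. Among cholesterol and lipid synthesis genes 13 of 26 rose, such as Idi1, 2.52-fold, and 1 fell, with 15 and 1 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.017), and adjusted p = 0.66 with an estimated correlation. Zinc transport and metallothionein genes rose in 6 of 13 cases and 11 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.0096), and adjusted p = 0.66 with an estimated correlation. Tgfbr3, a TGF-beta co-receptor, was 2.89 times lower and the signal transducer Smad3 1.58 times lower, and 4 of 16 TGF-beta receptor and trap genes fell while 1 rose, with 4 and 2 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.04), and adjusted p = 0.61 with an estimated correlation. Fgfr2, 2.25 times lower, was the 1 of 17 Klotho and FGF axis genes that fell, over all genes and adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.0062), and adjusted p = 0.61 with an estimated correlation.

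In all, 3348 of 11282 genes changed between OAC and HC, 2641 higher and 707 lower (78.9% higher), and 914 changed by a log2 size of at least 1. The median of all genes was 0.14 higher in OAC. Listed genes held 58.6 and 58.8% of the recovered reads in the HC libraries and 62.1 to 64.4% in the other groups. FPKM is scaled to all fragments, so this difference enters the shift. With median-of-ratios scaling the split was 1774 higher and 1311 lower (57.5% higher), with quantile normalization 1727 and 1274 (57.5%), and with voom on recovered reads 1807 and 986 (64.7%). Dlk1, a Notch ligand family member, was 6.79 times lower at 11.6 ± 0.29 against 78.9 ± 18.2 FPKM (limma, Benjamini-Hochberg adjusted p = 0.0011), and Myoc, which encodes myocilin, was 4.64 times lower. Lcn2, an acute phase protein of neutrophils, rose 8.6-fold, and 11 of 24 inflammatory genes rose, 13 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.0018), and adjusted p = 0.26 with an estimated correlation. Clock genes fell in 6 of 15 cases (6 adjusted over the list alone), among them Tef, 2.18 times lower (camera, Benjamini-Hochberg adjusted p = 3e-05), and adjusted p = 0.26 with an estimated correlation. Of 33 lists tested 18 were called, and 0 were with an estimated correlation, the lowest adjusted p being 0.26. In 7 lists that were not called the test pointed down while the median was above 0, at 0.28 for Wnt signalling, 0.49 for osteoblast and for hypertrophy genes, 0.05 for early response, 0.13 for hypoxia, 0.01 for protease inhibitors and 0.24 for synovium. The TGF-beta response list, also not called, had a median of -0.12 and a mean of 0.02. Under quantile and median-of-ratios scaling the test of the osteoblast, hypertrophy, hypoxia and synovium lists pointed up and that of the ribosomal list down. Among lists called by camera, limma's fry did not pass the Klotho and FGF axis (Benjamini-Hochberg adjusted p = 0.16), TGF-beta receptor (0.22), cartilage matrix (0.34), skeletal muscle (0.34) and oxidative phosphorylation (0.88) lists. The other called lists passed, at 0.00076 to 0.019. Kl stood at 0.042 ± 0.027 FPKM in OAC and 0.064 ± 0.00141 in HC (adjusted p = 0.89), and Tgfbr2 at 47.9 ± 9.79 and 29.9 ± 8.16 (limma, Benjamini-Hochberg adjusted p = 0.057). Without OAC replicate 2 the count fell to 2163 genes, and with array weights to 1974. Leaving out 1 library ended 44 of the 117 named calls.

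**Figure D3:**
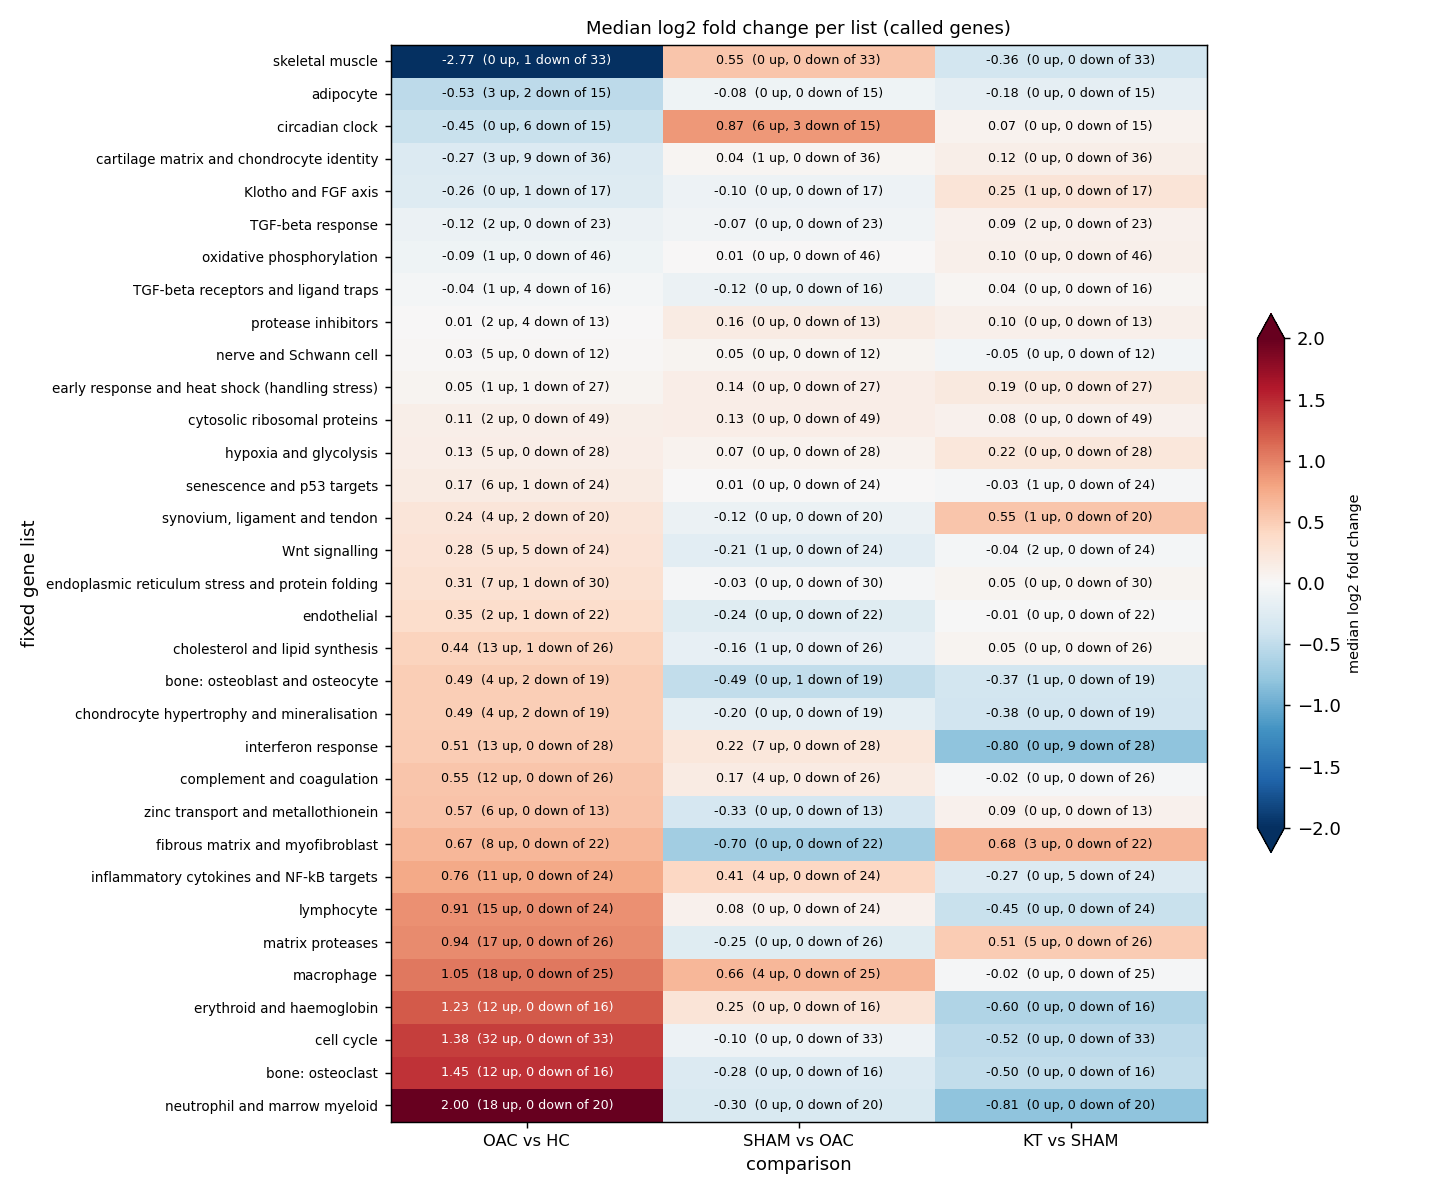
Median log2 fold change of the measured members of the 33 tested lists (rows) in the 3 main comparisons (columns), with the number of members called higher and lower. The interferon list runs from 13 members higher in OAC against HC and 7 higher in SHAM against OAC to 9 lower in KT against SHAM.

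The next comparison set SHAM, at 10 weeks with the GFP vector, against OAC at 4 weeks, so that time after injury and the vector differ together. A sequencing batch is also in part confounded with OAC. Chemokines and interferon response genes were among those that rose. Ubd, a ubiquitin-like modifier (NM_053299, chromosome 20 from 1876176 to 1878126), rose 133-fold, from 0.437 ± 0.429 FPKM in OAC (SD, n = 3) to 58.0 ± 13.2 in SHAM (SD, n = 3; limma, Benjamini-Hochberg adjusted p = 0.00014). The T cell chemokines Cxcl9 and Cxcl10 rose 63.2-fold and 30.0-fold, to 60.1 ± 35.7 and 27.0 ± 6.88 FPKM. Gbp2, a guanylate-binding protein, rose 10.2-fold. Of 28 measured interferon response genes 7 rose, 0 fell and 21 did not pass, or 9 higher when adjusted over the list alone (median 0.22, camera, Benjamini-Hochberg adjusted p = 1.8e-07), and adjusted p = 0.58 with an estimated correlation. At an unadjusted p under 0.05, 9 were higher and 3 lower (limma). Among those that rose were Gbp2, Gbp5, Psmb8, Psmb9, Tap1 and Bst2, while the log2 differences of Ifit1 (-0.39), Mx1 (0.20) and Rsad2 (0.00) did not pass. Beside them, erythroid genes had a median of 0.25 (camera, Benjamini-Hochberg adjusted p = 0.0079), and adjusted p = 0.71 with an estimated correlation, and neutrophil and marrow genes a median of -0.30 (adjusted p = 0.091 by camera with Benjamini-Hochberg).

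**Figure D4:**
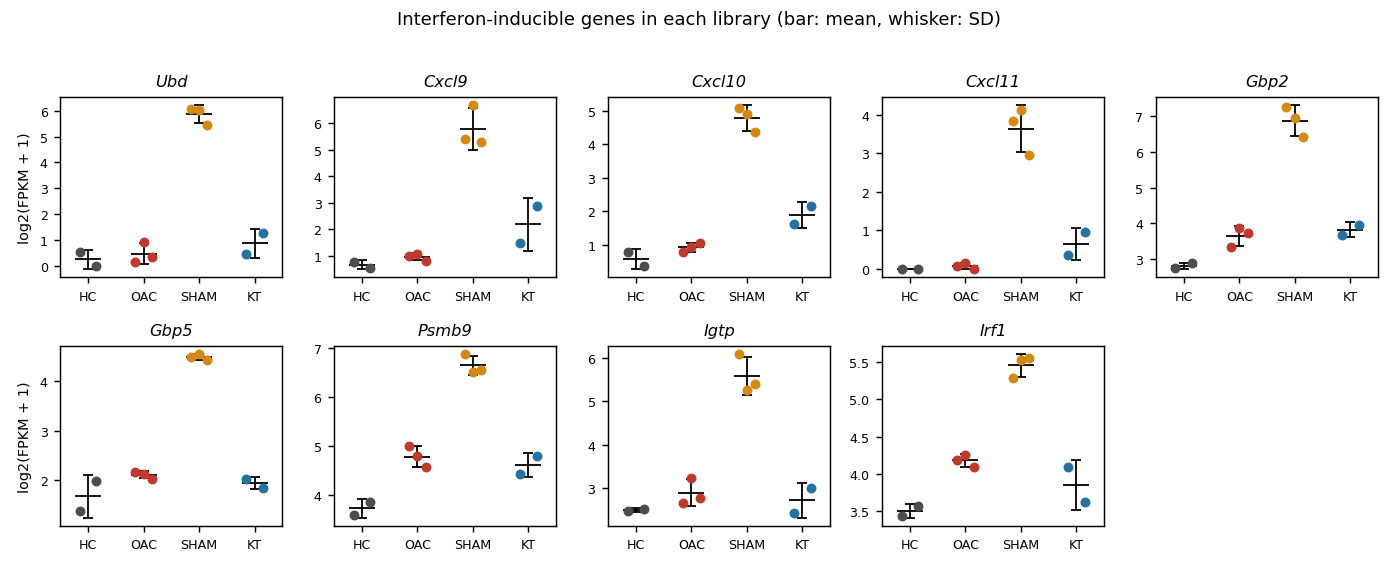
Expression of genes, most of them induced by interferon, as log2(FPKM + 1) per library (points) with the group mean and SD, by group on the x axis. The 3 SHAM libraries lie above every library of the other groups for Ubd, at a mean of 58.0 FPKM against 0.437 in OAC and 0.903 in KT.

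Some members of the inflammatory, complement and macrophage lists rose beside them. Ccl3, a macrophage chemokine, rose 2.63-fold and Irf1 2.5-fold, and 4 of 24 inflammatory genes rose, 9 adjusted over the list alone (median 0.41, camera, Benjamini-Hochberg adjusted p = 4.1e-11), a call that held with an adjusted p = 0.015 with an estimated correlation. C1s, a complement protease, rose 3.34-fold, with 4 of 26 complement genes, 11 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 1.8e-07), and adjusted p = 0.17 with an estimated correlation. Of 25 macrophage markers 4 rose, 13 adjusted over the list alone, among them RT1-Da and Cd74 of antigen presentation (median 0.66, camera, Benjamini-Hochberg adjusted p = 1.5e-15), and adjusted p = 0.18 with an estimated correlation. RT1-Da, at 688 ± 229 FPKM in SHAM (SD, n = 3), lost its call without OAC replicate 2 (limma, Benjamini-Hochberg adjusted p = 0.052) or 3 (0.058), and Cd74 without OAC replicate 2 (0.065), OAC replicate 3 (0.07), SHAM replicate 2 (0.054) or SHAM replicate 3 (0.065). Lymphocyte markers had 0 of 24 members called by limma over all genes and 2 higher when adjusted over the list alone, with 3 higher and 2 lower at an unadjusted p under 0.05, at a median of 0.08 (camera, Benjamini-Hochberg adjusted p = 0.21). Nos2, the inducible nitric oxide synthase, was below the filter at 69, 52 and 33 reads in the SHAM libraries and 2, 7 and 21 in the OAC libraries, a ratio of 5.48 with an exact binomial 95% interval of 3.69 to 8.4 that covers counting error only. Without the filter its change was 0.24 (limma, Benjamini-Hochberg adjusted p = 0.17).

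Clock genes moved in opposite directions. Arntl and Npas2, activators of the circadian loop, were 5.09 and 7.58 times lower in SHAM, Arntl at 2.69 ± 0.113 against 13.7 ± 3.23 FPKM (SD, n = 3 each; limma, Benjamini-Hochberg adjusted p = 0.00057). Tef and Per2, which peak in the other phase, rose by 1.40 and 1.34 on the log2 scale. Of 15 clock genes 6 rose, 3 fell and 6 did not pass, with 9 higher and 3 lower adjusted over the list alone (median 0.87, camera, Benjamini-Hochberg adjusted p = 2.4e-05), and adjusted p = 0.17 with an estimated correlation. Left out singly, the 6 OAC and SHAM libraries gave 4 to 6 called members, with 4 without OAC replicate 2, OAC replicate 3 or SHAM replicate 2. Among cartilage genes, Frzb rose 2.19-fold, and the log2 differences of Col2a1, Acan and Prg4, at -0.69, 0.70 and 0.77, did not pass (limma, Benjamini-Hochberg adjusted p = 0.66, 0.15 and 0.49). In the authors' deposited table Acan and Prg4 were called higher in SHAM (adjusted p = 0.00024 and 0.0025). Frzb lost its call without OAC replicate 2 (0.068), OAC replicate 3 (0.068), SHAM replicate 1 (0.059) or SHAM replicate 2 (0.074). Fibrous matrix genes had a median of -0.70 with 0 of 22 called by limma over all genes, 10 lower at an unadjusted p under 0.05 and 7 lower when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 1.9e-07), and adjusted p = 0.58 with an estimated correlation.

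Across the transcriptome 131 genes changed between SHAM and OAC, 104 higher and 27 lower, and 15 of 33 lists were called, 1 of them with an estimated correlation. The count was 73 without OAC replicate 1, 68 without OAC replicate 2, 57 without OAC replicate 3, 54 without SHAM replicate 2, 65 without SHAM replicate 3 and 324 with array weights. The further lists called had medians of -0.49 for osteoblast, -0.16 for cholesterol and lipid synthesis, 0.13 for ribosomal, 0.14 for early response, -0.25 for matrix protease, 0.16 for protease inhibitor, -0.33 for zinc transport (adjusted p = 0.58 with an estimated correlation for each) and -0.24 for endothelial genes (adjusted p = 0.64 with an estimated correlation). By limma's fry the inflammatory (Benjamini-Hochberg adjusted p = 0.00087), complement (0.029), clock (0.038), interferon (0.047) and macrophage (0.047) lists passed. The other lists called by camera did not, at 0.34 to 0.68. Of the 37 named calls 16 held whichever library was left out. Lists not called whose test pointed up while the median lay below 0 were TGF-beta response at -0.07, adipocyte at -0.08 and endoplasmic reticulum stress at -0.03, and the senescence list had a median of 0.01 and a mean of -0.06. Without HC replicate 1 the count was 163.

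Treatment was examined by setting KT against SHAM, both 10 weeks after papain. The delivered Klotho gene came first. Kl (NM_031336, chromosome 12 from 942974 to 987206) was at 12.2 ± 2.75 FPKM in KT (SD, n = 2) and 0.024 ± 0.0141 in SHAM (SD, n = 3; limma, Benjamini-Hochberg adjusted p = 1.1e-05). It had 3116 and 1938 reads in the KT libraries and 2, 5 and 8 in the SHAM libraries, a ratio of 508 with an exact binomial 95% interval of 308 to 909 for counting error only. Tgfbr2 (NM_031132, chromosome 8 from 124312829 to 124398864) stood at 36.8 ± 8.55 against 41.8 ± 4.39 FPKM and did not pass (limma, Benjamini-Hochberg adjusted p = 0.74), and whether reads of the delivered receptor would map to the rat transcript was not examined.

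Interferon genes were lower in KT. Ubd was 64.2 times lower, at 0.903 ± 0.735 FPKM in KT (SD, n = 2) against 58.0 ± 13.2 in SHAM (SD, n = 3; limma, Benjamini-Hochberg adjusted p = 0.00034). Cxcl9 was 14.6 times lower and Gbp2 9.03 times lower. Of 28 interferon response genes 9 fell and 19 did not pass, or 22 lower when adjusted over the list alone (median -0.80, camera, Benjamini-Hochberg adjusted p = 1.2e-18), and adjusted p = 0.25 with an estimated correlation. Among 24 inflammatory genes 5 fell, 6 adjusted over the list alone, with Irf1 3.15 times and Ccl3 3.41 times lower (camera, Benjamini-Hochberg adjusted p = 0.00067), and adjusted p = 0.18 with an estimated correlation. Markers of other cells moved too. Lymphocyte genes had a median of -0.45 with 0 of 24 called by limma over all genes, 12 lower at an unadjusted p under 0.05 and 6 lower adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 5.4e-05), and adjusted p = 0.29 with an estimated correlation. Neutrophil and marrow genes had a median of -0.81 with 0 of 20 called by limma over all genes or adjusted over the list alone and 13 lower at an unadjusted p under 0.05 (camera, Benjamini-Hochberg adjusted p = 6.6e-07), and adjusted p = 0.60 with an estimated correlation. Erythroid genes had a median of -0.60 (camera, Benjamini-Hochberg adjusted p = 3.6e-05), and adjusted p = 0.61 with an estimated correlation.

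Sfrp4, a secreted Wnt modulator (NM_053544, chromosome 17 from 47383983 to 47394065), rose 8.61-fold, from 10.4 ± 2.31 FPKM in SHAM (SD, n = 3) to 89.8 ± 29.0 in KT (SD, n = 2; limma, Benjamini-Hochberg adjusted p = 0.0025). In the Wnt signalling list Sfrp4 and the receptor Fzd1 rose among 24 measured members, 4 higher and 1 lower adjusted over the list alone, and the list was not called (camera, Benjamini-Hochberg adjusted p = 0.52). Lyve1, a hyaluronan receptor of lymphatic vessels and resident macrophages, rose 5.07-fold and Gpr34, a receptor of macrophages, 3.76-fold, while the macrophage list had a median of -0.02 with 0 of 25 called by limma over all genes, 4 higher and 8 lower at an unadjusted p under 0.05 and 2 higher adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.84). Col3a1 rose 3.64-fold to 797 ± 52.7 FPKM and the gelatinase Mmp2 2.92-fold to 267 ± 36.4 FPKM. Of 22 fibrous matrix genes 3 rose, Col3a1, the collagen Col5a3 and Loxl1, a lysyl oxidase family member, with 10 adjusted over the list alone (median 0.68, camera, Benjamini-Hochberg adjusted p = 7.6e-11), and adjusted p = 0.29 with an estimated correlation. Of 26 matrix proteases 5 rose, 12 adjusted over the list alone, among them Mmp3, 2.78-fold (median 0.51, camera, Benjamini-Hochberg adjusted p = 2e-08), and adjusted p = 0.26 with an estimated correlation. Of 20 measured synovium, ligament and tendon markers 1 rose, over all genes and adjusted over the list alone, Lum, a proteoglycan of fibrous tissue, at 1060 ± 258 FPKM in KT (SD, n = 2) against 423 ± 13.2 in SHAM (SD, n = 3; list median 0.55, camera, Benjamini-Hochberg adjusted p = 4.8e-06), and adjusted p = 0.18 with an estimated correlation. Lum lost its call without OAC replicate 2 (limma, Benjamini-Hochberg adjusted p = 0.056), OAC replicate 3 (0.07), any of the 3 SHAM libraries (0.11 to 0.13), KT replicate 1 (0.097) or KT replicate 2 (0.075). The calls of Col3a1, Mmp2 and Mmp3 were lost with fewer libraries while their changes stayed of like size. Without KT replicate 2 the log2 change went from 1.87 to 1.80 for Col3a1 (limma, Benjamini-Hochberg adjusted p = 0.26), from 1.54 to 1.68 for Mmp2 (0.13) and from 1.5 to 1.42 for Mmp3 (0.34), and each also lost its call without SHAM replicate 1, SHAM replicate 2, SHAM replicate 3 or KT replicate 1, at 0.05 to 0.17, Col3a1 without OAC replicate 3 (0.061), and Mmp3 without OAC replicate 1 (0.051), 2 (0.056) or 3 (0.087). Col5a3 and Loxl1 lost their calls without KT replicate 2 (0.34 and 0.27), any of the 3 SHAM libraries (0.097 to 0.13) or OAC replicate 3 (0.061 and 0.066), Col5a3 also without OAC replicate 1 (0.053) and Loxl1 without KT replicate 1 (0.063). Fzd1 lost its call without KT replicate 1 (0.051), KT replicate 2 (0.30), any of the 3 SHAM libraries (0.11 to 0.12) or OAC replicate 3 (0.07). With quantile normalization Col3a1 (0.053) and Mmp3 (0.069) were not called. The TGF-beta response list, which the soluble receptor would bear on, had 2 of 23 genes higher, Nox4 and Cdkn2b, and 2 adjusted over the list alone (median 0.09, camera, Benjamini-Hochberg adjusted p = 0.026), and adjusted p = 0.71 with an estimated correlation. Without KT replicate 2 Nox4 (0.35) and Cdkn2b (0.10) were not called, nor were they without OAC replicate 3, any of the 3 SHAM libraries or KT replicate 1, at 0.05 to 0.13. With the marrow score as a covariate the direction of the list turned.

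Cartilage genes were also compared between KT and SHAM. Col2a1 was at 2500 ± 991 FPKM in KT (SD, n = 2) and 2500 ± 918 in SHAM (SD, n = 3), Acan at 339 ± 43.7 and 333 ± 42.7, Sox9 at 22.8 ± 6.1 and 16.4 ± 3.05, Prg4 at 3270 ± 702 and 2160 ± 462, and Mmp13 at 224 ± 129 and 296 ± 146 FPKM. The log2 differences were 0.61 for Prg4, 0.44 for Sox9 and -0.38 for Mmp13. None of these passed (limma, Benjamini-Hochberg adjusted p = 1 for Col2a1, 0.95 for Acan, 0.44 for Sox9, 0.45 for Prg4 and 0.82 for Mmp13). Of 36 cartilage matrix genes 0 were called by limma, over all genes or adjusted over the list alone, and 1 was lower at an unadjusted p under 0.05, with a list median of 0.12 (camera, Benjamini-Hochberg adjusted p = 0.11). The test of this list pointed up, but it pointed down without KT replicate 2 and with the marrow score as a covariate. Nos2 had 12 and 2 reads in the KT libraries, a ratio to SHAM of 0.137 (exact binomial 95% interval 0.0732 to 0.237, for counting error only). Without the filter the change of Nos2 was -0.26 and did not pass (limma, Benjamini-Hochberg adjusted p = 0.17), while the authors' deposited table calls it lower in KT (log2 fold change -2.94, adjusted p = 0.032).

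In all 118 genes changed between KT and SHAM, 41 higher and 77 lower, and 15 of 33 lists were called, with 0 at an estimated correlation, where the lowest adjusted p was 0.18. The count was 72 without OAC replicate 3, 49 without SHAM replicate 1, 54 without SHAM replicate 2, 54 without SHAM replicate 3, 45 without KT replicate 2 and 73 in a fit of only the 2 groups. Leaving out 1 library ended 15 of the 31 named calls, with 15 lost without KT replicate 2 and 15 without SHAM replicate 1. With the marrow score as a covariate 27 genes were called, 2 higher and 25 lower. The further lists called had medians of 0.25 for the Klotho and FGF axis (adjusted p = 0.29 with an estimated correlation), -0.50 for osteoclast (0.71), 0.08 for ribosomal (0.86), 0.19 for early response (0.70) and 0.22 for hypoxia genes (0.60). The delivered Kl was the 1 called member of the Klotho and FGF axis list. Without it, a setting chosen after the data were seen, the list had a median of 0.21 (camera, Benjamini-Hochberg adjusted p = 0.0086), and adjusted p = 0.51 with an estimated correlation, with 0 of 16 members called by limma and 3 higher and 0 lower at an unadjusted p under 0.05. The test of the ribosomal and early response lists pointed down without KT replicate 2 and with the marrow score as a covariate, and that of the hypoxia list with the marrow score. The early response score was 0.57 in KT replicate 2 and 0.02 in KT replicate 1. Cell cycle genes had a median of -0.52 (camera, Benjamini-Hochberg adjusted p = 1.2e-08), and adjusted p = 0.70 with an estimated correlation, and were called in the other direction with the marrow score as a covariate. Lists not called whose test pointed up at a median below 0 were Wnt signalling at -0.04, osteoblast at -0.37, endothelial at -0.01, macrophage at -0.02, senescence at -0.03 and skeletal muscle at -0.36. The endoplasmic reticulum stress list had a median of 0.05 and a mean of -0.01, and under quantile and median-of-ratios scaling the test of the osteoblast list pointed down. By limma's fry the inflammatory (Benjamini-Hochberg adjusted p = 0.0044), interferon (0.0084), synovium (0.021), matrix protease (0.038) and lymphocyte (0.047) lists passed. So did the Klotho and FGF axis list with the delivered Kl (0.018). The other lists called by camera did not, at 0.11 to 0.79.

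The genes that were higher in SHAM than OAC overlapped with those lower in KT than SHAM. Of 104 and 77 genes, 52 were shared, against 0.71 for independent lists and 0 in 100 simulations of unchanged groups that shared the SHAM libraries. Unchanged groups have almost no calls to share, so the simulated count does not measure what shared libraries add to the overlap. Splitting the 3 SHAM libraries would not leave 2 on each side, so part of the excess may come from shared controls. Across genes, which are not independent replicates, the changes correlated at -0.38 against -0.45 in simulations, with a covariance of -0.0377 against -0.0249, a difference of -0.0128.

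KT was also set against OAC, where the time after injury, the vectors and in part a sequencing batch differ. Cxcl13, a B cell chemokine, was at 260 ± 178 FPKM in KT (SD, n = 2) and 9.7 ± 9.76 in OAC (SD, n = 3), 26.8-fold higher (limma, Benjamini-Hochberg adjusted p = 0.033). Trem2, a lipid receptor of macrophages, rose 5.42-fold and Sfrp4 6.67-fold. In the authors' deposited table Cxcl13 and Trem2 were also higher in SHAM than in OAC (log2 fold change 4.41 and 1.8). Arntl and Npas2 were 4.54 and 5.13 times lower. Ubd stood at 0.903 ± 0.735 against 0.437 ± 0.429 FPKM (limma, Benjamini-Hochberg adjusted p = 0.55). A total of 45 genes changed, 29 higher and 16 lower, with 2071 at an unadjusted p under 0.05. Of the 29 higher genes 14 were also called higher in SHAM against OAC. Of the 16 lower genes 4 were also lower there. Both comparisons share the OAC libraries. Camera called 22 of 33 lists, and 0 with an estimated correlation. List medians were -1.19 for neutrophil and marrow, 0.76 for macrophage, -0.42 for lymphocyte and -0.53 for interferon response genes. Genes in this comparison were chosen after their values were seen.

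Against healthy cartilage, 2986 genes changed in SHAM (2368 higher, 618 lower) and 2057 in KT (1611 higher, 446 lower). With median-of-ratios scaling the splits were 1708 and 1223 for SHAM and 1059 and 792 for KT. The counts fell to 1968 in SHAM without SHAM replicate 2, and in KT to 972 without KT replicate 1 and 1116 without KT replicate 2. With array weights 1628 genes were called in SHAM and 493 in KT, in fits of only the 2 groups 1970 and 10, and with the marrow score as a covariate 30 and 817. Mmp3 was 4.78-fold higher in SHAM and 13.3-fold in KT, and Col3a1 3.34-fold and 12.2-fold. Col2a1 was 2.57-fold higher in SHAM (limma, Benjamini-Hochberg adjusted p = 0.039) and 2.58-fold in KT, where it missed the threshold (0.067), and Mmp13 was 4.24-fold higher in SHAM (0.046) and 3.21-fold in KT (0.14). Acan changed by -0.28 and -0.25 and did not pass in either. The effects in SHAM and KT were compared only through the direct test of KT against SHAM.

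Whether disease genes moved back under treatment was tested with limma's fry. The 2641 genes raised in OAC had a median change of -0.17 in KT against SHAM, 1847 of them (69.9%) below 0, and the 707 lowered genes had a median of 0.02, with 389 (55%) above 0. Neither set passed (limma's fry, Benjamini-Hochberg adjusted p = 0.086 for the raised and adjusted p = 0.66 for the lowered genes), and the median of all genes was -0.04. The difference between the medians of the 2 sets, for which no test was run, was 0.19. The raised set passed limma's fry with quantile normalization (median -0.23, adjusted p = 0.019), median-of-ratios scaling (median -0.24, adjusted p = 0.023), array weights (median -0.24, adjusted p = 0.045), the 200 genes of smallest p per direction (median -0.38, adjusted p = 0.0092) and without KT replicate 1 (median -0.28, adjusted p = 0.0043). Its median was -0.07 without KT replicate 2 (fry adjusted p = 0.57) and -0.12 without HC replicate 2 (fry adjusted p = 0.18), where the difference of medians was 0.09 and 0.11. The neutrophil and erythroid lists, which rose in OAC, had medians of -0.81 and -0.60 in KT against SHAM, and the marrow score was -0.52 in KT replicate 2, 0.03 in KT replicate 1 and 0.27 to 0.64 in SHAM. The lowered set did not pass fry under any of these settings (adjusted p = 0.30 to 0.96).

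The authors' deposited table, made with DESeq2 from counts, lists 3716 changed genes for OAC against HC (1922 higher, 1794 lower), 526 for SHAM against OAC (371 and 155), 527 for KT against SHAM (252 and 275) and 2960 for SHAM against HC (1767 and 1193). Of the genes called here, 2478 of 3348, 131 of 131, 117 of 118 and 2216 of 2986 are called in the same direction in the authors' deposited table, and 0 have the opposite sign there. Across genes the log2 fold changes correlated at 0.907 to 0.948. KT against HC and KT against OAC are not in that table.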

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

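The tests of immune cells, vector particles, groups without a vector, a single library and the time of day were chosen after the result was seen, as was the use of the planned scaling and left-out libraries to weigh an explanation. The marrow covariate was added after the data were seen, and its test was set before its own result.

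The inflammatory list differed between SHAM and OAC with an estimated correlation (camera, Benjamini-Hochberg adjusted p = 0.015). Its difference from HC was thus not alike in these groups, which differ in the weeks since papain, the vector and in part a sequencing batch. Adamts5, an aggrecanase, lay above the HC mean in all 3 OAC libraries and below it in all 3 SHAM libraries, with a log2 difference of -0.42 between the groups. It was 3.57 ± 0.52 FPKM in OAC and 2.43 ± 0.48 in SHAM, and the difference did not pass (limma, Benjamini-Hochberg adjusted p = 0.51).

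The 7 interferon list members that rose in SHAM against OAC had a median log2 change of 1.87 there and -2.04 in KT against SHAM. They were chosen for their rise in SHAM, whose libraries both comparisons share, so these values are set in part by the choice. The medians of the whole list were 0.22 (95% bootstrap interval -0.04 to 0.53) and -0.80 (-1.06 to -0.55). More immune cells of every kind in SHAM tissue stays open: the macrophage list had medians of 0.66 (95% bootstrap interval 0.31 to 1.05) and -0.02 (-0.38 to 0.29) in these comparisons and the lymphocyte list 0.08 (-0.18 to 0.21) and -0.45 (-0.54 to -0.25). The neutrophil and marrow list went the other way in SHAM against OAC, at -0.30 (-0.39 to -0.16), and fell by 0.81 (-0.95 to -0.73) in KT against SHAM, but its list scores overlapped at 0.27 to 0.71 in SHAM and 0.47 to 0.96 in OAC, so its first change is not beyond the spread between libraries. Vector particles of any cargo, with nothing acting against them, would raise the interferon list in KT too. Its median over all members in KT against OAC was instead -0.53 (-0.61 to -0.30), though the labels give no vector dose. These intervals resample genes and carry no spread between libraries. By library, the interferon list scores were -0.41 and -0.44 in KT and -0.10 to 0.30 in OAC. The design has 0 groups at 10 weeks without a vector, so disease progression or a vector response held back by the treatment and a reaction to the GFP cargo cannot be told apart.

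Raised genes outnumbered lowered genes in OAC against HC, at 2641 to 707. The share raised was 57.5% with median-of-ratios scaling against 78.9% as deposited. That scaling centres the typical gene near no change, with a median of all genes of -0.01 against 0.14 as deposited. A lower share therefore follows whether the shift came from the scaling of the deposited values or from the tissue. It does not decide between them. More blood and marrow in the dissected OAC tissue stays open: with the marrow score as a covariate the median log2 change of the raised genes went from 0.72 to 0.41 (95% bootstrap interval 0.38 to 0.43), limma called 0 genes, and genes at an unadjusted p under 0.05 went from 4730 to 2157. The score lies at -0.87 and -1.43 in HC and between 0.19 and 0.77 in OAC, so it and the group cannot be told apart, and a disease effect on these genes remains untested.

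Clock genes of opposite phase moved in opposite directions between OAC and SHAM, with 9 members called. Leaving out 1 OAC or SHAM library left at least 4 called, fewer than 9 but not few enough to lay the difference on 1 library. Collection at another time of day may account for it, since in KT against SHAM limma called 0 clock members and 0 were at an unadjusted p under 0.05. The labels give no time of day. Its effect cannot be told apart from that of the weeks since injury, the vectors or a sequencing batch.

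The 6 OAC and SHAM libraries make 10 splits of 3 against 3, so the share of splits with a result as large is never under 0.1. The real split called 131 genes and the highest of the others 0, so only the real split gave as many. For lists the real split called 15 and the highest of the others 16, and 6 of the 10 splits, the real one among them, gave at least 15. The number of lists called therefore does not set the real split apart from the others.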

How the results depend on the processing

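The fits by voom, without haemoglobin and with the marrow covariate were chosen after the data were seen. Named genes that were called kept their direction under the pseudocounts, the scalings, the replicate block and the left-out libraries, while genes such as Col2a1, Runx2, Slc39a8, Mmp3, Tgfbr2, Acan, Mmp13 and Col1a1 changed sign in a comparison in which they were not called. With quantile normalization 11 of 117 named calls in OAC against HC, 2 of 37 in SHAM against OAC and 3 of 31 in KT against SHAM were lost, and with median-of-ratios scaling 10, 4 and 1. Array weights called 1974 genes in OAC against HC, 324 in SHAM against OAC, 1628 in SHAM against HC and 493 in KT against HC. A fit of only the groups compared called 73 genes in KT against SHAM, 1970 in SHAM against HC and 10 in KT against HC, where fewer libraries estimate the spread. A log2 change of at least 1 left 914, 913 and 515 genes in OAC, SHAM and KT against HC, a stricter threshold by construction. The authors' deposited table gave 526 genes in SHAM against OAC and 527 in KT against SHAM. The marrow covariate left 0 genes in OAC against HC by limma (2157 at an unadjusted p under 0.05), 27 in KT against SHAM, 30 in SHAM against HC and 817 in KT against HC, and gives no reversal value. An estimated correlation left 0, 1 and 0 lists in the main comparisons. That setting changes more than the correlation. The inflammatory list had an estimate of 0.011, near the preset 0.01. Its adjusted p still went from 4.1e-11 to 0.015 in SHAM against OAC and from 0.00067 to 0.18 in KT against SHAM (camera, Benjamini-Hochberg). The raised set passed limma's fry with quantile normalization, median-of-ratios scaling, array weights and the 200 genes of smallest p per direction, where the untested difference between the medians of the lowered and raised sets was 0.28, 0.28, 0.27 and 0.40. Except where stated, the cause was not tested.

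With each library left out in turn, the count was 2163 to 3331 in OAC against HC, 54 to 163 in SHAM against OAC, 45 to 122 in KT against SHAM, 1968 to 2969 in SHAM against HC and 972 to 2205 in KT against HC. Lists numbered 15 to 19, 15 to 19 and 14 to 17 in the main comparisons, and the difference of medians of the reversal was 0.09 to 0.30. A group of 2 keeps a lone library then, which is assumed to vary like the other groups. Fits with edgeR and DESeq2 on recovered reads were not run.

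The replicate numbers do not pair the libraries. Of 13 pairs with the same number 4 had deviations correlated over 0.1, in a range of -0.48 to 0.49, and 3 of 10 libraries correlated best with their own number. With the replicate block 2206 genes were called in OAC against HC, 107 in SHAM against OAC, 80 in KT against SHAM, 1951 in SHAM against HC and 1116 in KT against HC, with 19, 16 and 15 lists in the main comparisons and a difference of medians of 0.26. Depth limits low genes such as Nos2, at 0 to 69 reads per library, and Kl outside KT, at 2 to 15 reads.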

Other observations

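The RT1 family and all tests below were chosen after the result was seen. Genes of the rat major histocompatibility complex, which present antigen, were counted because members had been seen to change, so the counts are no independent evidence of a direction. Of 34 measured RT1 genes 15 rose in SHAM against OAC at a median log2 change of 1.10 and 15 fell in KT against SHAM at a median of -1.34 (limma). In KT against OAC limma called 0 of them, with 4 higher and 6 lower at an unadjusted p under 0.05, at a median of -0.29. Members of this family are near-identical copies that can share reads and are counted here as separate members, so the values of single members are uncertain and the counts are not of independent genes.

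Genes called at 4 and at 10 weeks overlapped. OAC and SHAM shared 1994 raised and 443 lowered genes against HC, where independent lists would share 550 and 39, and simulated unchanged groups with the same HC libraries 0.02, a count that does not measure what shared libraries add, since such groups have almost no calls. The covariance of the changes was 0.32 against 0.0369 in simulations, a difference of 0.283. Splitting the HC pair would leave single libraries, so part of the excess can come from shared controls. The marrow score was also higher in both groups, at 0.19 to 0.77 in OAC and 0.27 to 0.64 in SHAM against -0.87 and -1.43 in HC. With it as a covariate limma called 0 genes in OAC against HC, with 2157 at an unadjusted p under 0.05, and 30 in SHAM against HC, so the overlap is not separated from a shared tissue content.

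A hypothesis was that the delivered soluble receptor lowered TGF-beta target genes. The TGF-beta response list had a median log2 change of 0.09 in KT against SHAM with a 95% bootstrap interval of -0.06 to 0.34, which leaves the hypothesis open.

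Another hypothesis was that more macrophages in KT tissue raised Lyve1, Gpr34 and Apoe, whose median log2 change was 1.67. Apoe lost its call in KT against SHAM without any single library other than KT replicate 1, for example without KT replicate 2 (log2 change 1.16 against 1.57, limma, Benjamini-Hochberg adjusted p = 0.36). The median of the macrophage list in KT against SHAM was -0.02 (95% bootstrap interval -0.38 to 0.29). Of its 25 members 4 were higher and 8 lower at an unadjusted p under 0.05 (limma). By library its scores were 0.44 and 0.75 in KT and 0.35 to 0.92 in SHAM. These values argue against a rise of macrophage markers of the size seen in Lyve1, Gpr34 and Apoe. A smaller rise is not decided, since the list holds RT1-Da, RT1-Ba and Cd74 of antigen presentation. Of 34 RT1 genes 15 fell in the same comparison. In KT against OAC the macrophage list had a median of 0.76 (0.54 to 1.19). A change of macrophage state could not be tested. The set of genes was altered after its result was seen: with Trem2, a 4 gene set, the median was 1.62.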
